A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

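The samples, their groups, the tests and most alternatives were written down before the data were examined. SMIT was carried out in the wild type and in strains deleted for NPL3, GBP2, RTT103, THO2, PUB1 or HTZ1 (14 libraries), and in Nab2-AA and Control-AA at 0, 10 and 30 min of rapamycin at 1 ug per ml (6 libraries). Long reads came from Nab2-AA and Control-AA at 10 min (4 libraries). Per the labels, cells grew in rich medium at 30 C, nascent RNA was taken from chromatin, treated with DNase and depleted of poly(A) RNA. For SMIT a 3' adapter with 5 random bases was ligated, and gene-specific primers and PCR followed. For long reads ribosomal RNA was removed with an exonuclease that spares capped RNA, cDNA was made by strand switching and PCR, and flow cells ran for 48 hours.

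The SMIT files hold, per the labels and the file headers, read counts per gene and 3' end position, deposited by the authors as spliced and unspliced reads, with a corrected fraction spliced beside them. The authors' difference tables give a score per gene and strain whose scale is not stated. The authors' long-read table gives a fraction spliced per gene and library without the reads behind it. The deposited long-read alignments are genome coordinates of single reads near intron-containing genes, and the selection of these reads is not stated. Per the submitters' processing notes, HISAT2 2.1.0, cutadapt 1.9.1, minimap2 2.17, SAMtools 1.9 and bedtools 2.29.2 were used with the build sacCer3, with no role or order given; removal of PCR copies is not stated.

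SMIT reads downstream of the 3' splice site were summed per gene for tests. For fractions, positions were placed in bins of 30 nt with at least 10 reads, and the fractions of the bins were averaged with equal weight. Genes needed 20 reads in every library and listed positions that reached 200 nt. Of 53 genes in the deletion series 5 were left out (RPS9B, RPS13, SAC6, RPL20A and NOG2) and 48 used; of 59 in the anchor-away series 2 were left out (RPS0A and RPL20A) and 57 used. Long-read introns were found from alignment gaps, because no intron annotation was given: 205 introns in 198 genes. A read was spliced when its gap matched both intron ends within 10 nt and unspliced when it covered 90% of the intron. A chimeric read overlapped the intron-containing gene and an upstream gene on the same strand by at least 50 nt each, and a read ended beyond the gene when its 3' end lay more than 250 nt past the coding end. Gene spans, strands and names came from the reference gene table. Between 5.96% and 6.24% of read names per library occurred on both strands.

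Strain effects on splicing were tested with edgeR 4.0.16 (quasi-likelihood F test) as the interaction of strain with splicing state, with 1 term per library and Benjamini-Hochberg adjustment at 0.05 within each comparison. The same model served chimeric reads and reads ending beyond the gene, the latter added after the shares were seen. DESeq2 1.42.0 and limma 3.58.1 were alternatives, in R 4.3.3. Shares per library were given exact binomial intervals and compared by exact permutation. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9. The anchor-away time course has 1 library per strain and time and was described without a test.

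Named genes followed a rule fixed in advance. In deletion strains, where none passed, the 2 genes with the largest change per direction and equal sign in both replicate numbers are named with values only. In the time course the 10 most negative and 5 most positive differences at 30 min with equal sign at 10 min and at least 100 reads are named. In long reads up to 12 introns per direction that passed are named, then up to 10 genes with a changed chimeric share and, where fewer than 5 passed, the 5 with the most chimeric reads in Nab2-AA. ACT1 was always included, as were members of the gene lists with the most reads. The lists were RP and non-RP genes, snoRNA host introns, cytoskeleton, membrane traffic, ubiquitin and proteasome, RNA processing and export, mitochondrial respiratory and meiotic genes, with genes of 2 introns for long reads. Exceptions, named after their values were seen, were SEC27, NMD2, DBP2 and GLC7 at an unadjusted p under 0.05, RPL19B and RPS7A among introns, and the genes named for reads ending beyond the gene.

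The pipeline was tested on simulated data in 20 draws per setting. Of changed introns, 9.38% were recovered at a log2 odds ratio of -1 and 43.2% at -2; of genes with a changed chimeric share, 5% at 2 and 55% at 4; of genes with a changed share of reads ending beyond the gene, 10% at 1 and 46.6% at 2. False calls were at most 0.35 per draw. A change of -0.1 in the position-averaged fraction was recovered as -0.102. In all, 549 alternative settings were computed over 41 results.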

Results

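Splicing during transcription was measured in budding yeast by a pair of assays of RNA taken from chromatin. Single Molecule Intron Tracking (SMIT) joins an adapter to the 3' end of nascent RNA, which marks where RNA polymerase II stood, and gene-specific primers then report whether the intron upstream of that position was still present. Nanopore long reads of the same kind of RNA show intron, start and end in a single molecule. The 24 samples fell into 15 groups. SMIT covered the wild type and 6 deletion strains with 2 libraries each. It also covered an anchor-away pair, in which rapamycin withdraws an FRB-tagged protein from the nucleus, at 0, 10 and 30 min with 1 library per strain and time. Nab2-AA carries tagged Nab2, a nuclear poly(A)-binding protein, and Control-AA is the parental strain given the same drug. Nab2-AA is recorded as MATalpha and Control-AA as MATa, so mating type differs along with the tag in every comparison of these strains. Long reads came from both anchor-away strains after 10 min of rapamycin, with 2 libraries each. Reads downstream of the 3' splice site numbered 699678 to 2839057 per library in the deletion series and 1263469 to 1640980 in the anchor-away series. The long-read files gave 32107 and 11485 alignments for Nab2-AA and 10042 and 14264 for Control-AA. The labels do not say that libraries of a group came from separate cultures. The p-values thus cover no more than counting error and the spread between these libraries, which may be technical. edgeR estimates that spread with information shared over genes or introns, so a p-value need not reflect the spread of its own gene. In long reads ARP9 passed with 52.1% ± 26.5 spliced in Control-AA (edgeR adjusted p = 0.0271). Reads amplified by PCR are not independent molecules, so the intervals given here cover counting error only. None of the deleted genes, nor NAB2, contains an intron, so none was measured and the strain labels could not be checked from them. Reads on HMRA1, an intron gene of MATa cells, numbered 0 in every long-read library, so this gene could check no label either.

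The deletion series asked whether proteins that bind nascent transcripts or chromatin alter the fraction of transcripts spliced while polymerase is still on the gene. Across 48 genes, the fraction spliced of the gene coding for actin, ACT1, was 0.964 ± 0.0292 in the wild type and lay between 0.9497 and 0.968 in the 6 deletion strains. The median change over genes was small in each strain and differed in sign between its 2 libraries when both were set against the wild-type mean. It was -0.113 and 0.0347 in npl3, -0.0599 and 0.0275 in gbp2, -0.0878 and 0.0351 in rtt103, -0.00530 and 0.0580 in tho2, -0.0584 and 0.0656 in pub1, and -0.0344 and 0.0122 in htz1, where the first value is replicate 1. With the authors' correction both libraries lay above 0 in tho2 (0.0569 and 0.109), pub1 (0.00938 and 0.103) and htz1 (0.00934 and 0.0592), and the signs still differed in the other strains. The wild-type libraries themselves differed by a median of -0.0409, replicate 1 minus replicate 2, with 43 of 48 genes lower in replicate 1. Per the labels replicate 2 of all 7 strains shared a run, while replicate 1 of the deletion strains lay in another run and replicate 1 of the wild type in its own. Within the shared run, the median change was 0.00522 in npl3, -0.000101 in gbp2, 0.00165 in rtt103, 0.0304 in tho2, 0.0312 in pub1 and -0.0108 in htz1. These medians were not tested; an exact permutation test of 2 against 2 libraries cannot give a two-sided p below 0.3333.

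**Figure D1:**
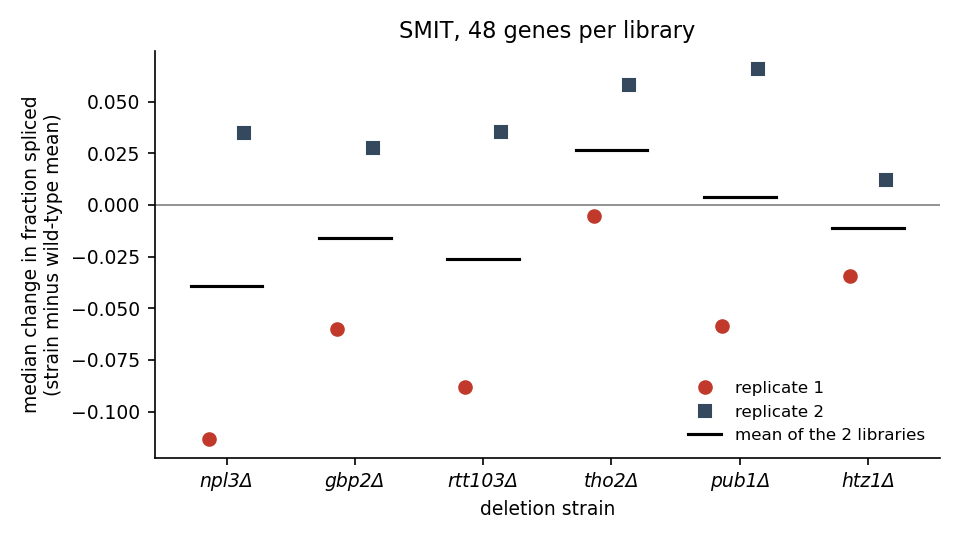
Each marker is the median over 48 genes of the change in fraction spliced (vertical axis, strain minus wild-type mean) in 1 SMIT library of the deletion strain named on the horizontal axis, and the bar is the mean of the 2 libraries. Replicate 1 lies below 0 and below replicate 2 in all 6 strains, from -0.113 in npl3 to -0.00530 in tho2.

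In npl3, which lacks an RNA-binding protein of the SR family, RUB1, a ubiquitin-like modifier, had a spliced fraction of 0.512 ± 0.0848 against 0.671 ± 0.0639 in the wild type (SD, n = 2). ARP9, a subunit shared by chromatin remodelling complexes, stood at 0.462 ± 0.101 against 0.598 ± 0.0149. QCR10, a subunit of the mitochondrial cytochrome bc1 complex, stood at 0.657 ± 0.111 against 0.529 ± 0.180, and MAF1, a repressor of RNA polymerase III, at 0.472 ± 0.0262 against 0.340 ± 0.0730. None of these passed the test. edgeR's quasi-likelihood test called 0 of 48 genes, with 2 at an unadjusted p under 0.05 (SEC27, lower, and NMD2, higher), and the smallest adjusted p was 0.726; DESeq2 and limma also called 0. All 6 ribosomal protein (RP) genes had a log2 odds ratio below 0, with a median of -0.96, and 0 were called, also when adjusted over the list alone. This was not particular to npl3: 5 of 6 lay below 0 in gbp2 (median -0.68), htz1 (-0.80) and pub1 (-0.37), against the same wild-type libraries.

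In gbp2, which lacks an RNA-binding protein of mRNA export, RPO26, a subunit shared by the nuclear RNA polymerases, had a spliced fraction of 0.609 ± 0.0737 against 0.726 ± 0.00936 in the wild type. IST1, a regulator of endosomal sorting, had 0.575 ± 0.0563 against 0.674 ± 0.0129. UBC4, a ubiquitin-conjugating enzyme, had 0.722 ± 0.0644 against 0.517 ± 0.0350, and OM14, a protein of the mitochondrial outer membrane, 0.804 ± 0.0937 against 0.730 ± 0.110 (SD, n = 2). edgeR called 0 genes with 1 at an unadjusted p under 0.05 (DBP2), and DESeq2 and limma called 0; the smallest adjusted p in edgeR was 0.992. In rtt103, which lacks a termination factor that binds the polymerase tail, RPO26 had 0.604 ± 0.0427 and BIG1, an endoplasmic reticulum protein needed for cell wall glucan, 0.445 ± 0.0642 against 0.577 ± 0.0751. UBC4 had 0.746 ± 0.0661 and SAR1, the GTPase of COPII vesicle coats, 0.948 ± 0.0151 against 0.853 ± 0.0752. edgeR called 0 genes in rtt103, with 1 at an unadjusted p under 0.05 (GLC7, a protein phosphatase subunit), against 1 higher gene each with DESeq2 and limma; the smallest adjusted p in edgeR was 0.652.

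In tho2, which lacks a subunit of the THO complex that links transcription to export, 25 of 48 genes lay above the wild type in both replicate numbers and 6 lay below. UBC4 had a spliced fraction of 0.834 ± 0.1197 against 0.517 ± 0.0350 and QCR10 0.759 ± 0.0947 against 0.529 ± 0.180 (SD, n = 2). CMC4, a mitochondrial intermembrane space protein, had 0.103 ± 0.0156 against 0.192 ± 0.0273, and RPS9A, a protein of the small ribosomal subunit, 0.855 ± 0.158 against 0.944 ± 0.0319. The change in RPS9A came from replicate 1 (-0.126, against -0.000781 in replicate 2), and its mean turned to 0.0302 with the authors' correction. All 6 measured genes of the ubiquitin and proteasome list and all 4 of the mitochondrial respiratory list had log2 odds ratios above 0, with medians of 0.64 and 0.82, and 0 passed in either list, also adjusted over the list alone. The lists moved with the strain as a whole, where only 11 of 48 genes lay below 0 and the median of the 42 non-RP genes was 0.57. edgeR called 0 genes, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.263; DESeq2 and limma called 1 higher gene each. The count depended on how replicates were modelled: edgeR called 3 higher genes in tho2 with a replicate block (EFB1, GLC7 and QCR10). In settings added after the data were seen it called 2 in tho2 and 1 in gbp2 with the run in the labels as a block, and 23 in tho2 and 3 in rtt103 with the authors' correction and the replicate block.

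In pub1, which lacks a poly(U)-binding protein, UBC4 had 0.856 ± 0.0960 and its close relative UBC5 0.677 ± 0.0966 against 0.554 ± 0.0417 in the wild type (SD, n = 2). IST1 had 0.568 ± 0.0997 and ACT1 0.954 ± 0.0415, the only 2 genes lower in both replicate numbers, against 16 higher; with the authors' correction the mean change of ACT1 turned from -0.0118 to 0.0306. In htz1, which lacks the histone variant H2A.Z, RPO26 had 0.641 ± 0.0196 and SEC14, a phospholipid transfer protein of the Golgi, 0.792 ± 0.106 against 0.867 ± 0.0101. UBC4 had 0.731 ± 0.117 and SEC17, which takes SNARE complexes apart, 0.726 ± 0.0144 against 0.677 ± 0.0841. edgeR called 0 genes in either strain, with 2 at an unadjusted p under 0.05 in pub1 and 0 in htz1, and smallest adjusted p of 0.926 and 0.891. DESeq2 called 0 in both, limma called 1 higher gene in each, and edgeR on only the wild type and the strain called 2 in pub1. Because all 6 strains were set against the same pair of wild-type libraries, the recurrence of UBC4 is not independent from strain to strain. In every strain, 0 genes passed in each of the fixed lists, also adjusted over the list alone, which held 6 RP genes, 5 of membrane traffic, 6 of ubiquitin and proteasome, 4 mitochondrial respiratory, 3 of RNA processing and export, 2 each of snoRNA host introns and cytoskeleton, and 0 meiotic genes. Changes simulated in 48 genes were recovered at a rate of 1% for a log2 odds ratio of 1, 14.5% for 2 and 76.5% for 4 in this fit, which has no term for the run.

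The anchor-away time course asked how soon splicing moved once Nab2 left the nucleus. In 57 genes, the median change in fraction spliced from 0 min was -0.0493 at 10 min and -0.0197 at 30 min in Nab2-AA, with 46 and 43 genes below 0. In Control-AA it was -0.00153 and -0.00280, with 39 and 38 genes below 0. The fraction was lower than at 0 min by more than 10 percentage points in 17 and 16 genes of Nab2-AA, and in 1 and 0 genes of Control-AA. UBC9, the SUMO-conjugating enzyme, went from 0.631 through 0.519 to 0.330 in Nab2-AA and from 0.703 through 0.688 to 0.687 in Control-AA. QCR10 went from 0.631 through 0.463 to 0.369 against 0.670, 0.630 and 0.657.

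Relative to Control-AA, the change at 30 min was -0.284 for UBC9 (95% counting interval -0.322 to -0.246) and -0.272 for PCC1 (-0.319 to -0.224), a subunit of the KEOPS complex that modifies tRNA. It was -0.248 for QCR10, -0.234 for RUB1, -0.190 for OM14 and -0.184 for UBC13, which builds K63-linked ubiquitin chains. RPS14B, a small-subunit ribosomal protein, had -0.170, ERD2, the receptor that returns proteins to the endoplasmic reticulum, -0.152, and DTD1, a D-aminoacyl-tRNA deacylase, -0.150. RPL2A, a protein of the large ribosomal subunit, had -0.205, of which part came from Control-AA, where the fraction stood at 0.743, 0.929 and 0.804 against 0.874, 0.748 and 0.729 in Nab2-AA. The largest positive values were 0.324 for SAC6 (0.2799 to 0.369), the actin-bundling fimbrin, 0.184 for NMD2, a factor of nonsense-mediated decay, and 0.172 for IST1. NSP1, a nuclear pore protein, had 0.0911 and MAF1 0.0815. SAC6 in Nab2-AA went from 0.404 through 0.638 to 0.685, and in Control-AA from 0.547 through 0.478 to 0.504. Long reads, taken at 10 min only, compare the strains and not the times. They gave 39.9% ± 0.176 spliced in Nab2-AA against 41.3% ± 5.35 in Control-AA (SD, n = 2). SMIT at 10 min had 0.638 against 0.478, an excess in Nab2-AA that long reads did not show. The SMIT fraction of ACT1 was near 1 throughout, at 0.976, 0.968 and 0.973 in Nab2-AA, and its difference at 30 min was 0.00236 (-0.00796 to 0.0127).

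By list, the 6 measured genes of the ubiquitin and proteasome group had a median difference of -0.0796 at 10 min and -0.143 at 30 min, at percentiles 21.7 and 3.81 of 10000 random lists matched in 3 classes of read number. PRE3, a proteasome subunit, had -0.102 at 30 min, while UBC4 had 0.0542, with Control-AA values of 0.717, 0.457 and 0.635. The 4 mitochondrial respiratory genes had medians of -0.0891 and -0.0732 (percentiles 29.3 and 43.9), and the 5 membrane traffic genes -0.0541 and -0.0661 (55.1 and 44.6), among them SEC14 at -0.0661 after 30 min. The median of the 13 RP genes was -0.00110 and -0.000470 (90.3 and 55.9), although RPL2A, RPS14B (-0.131 and -0.170) and RPS9A (-0.0859 and -0.0394) lay well below 0, against -0.0411 and -0.0298 for the 44 non-RP genes (87.6 and 85.2). The 3 RNA processing and export genes had medians of 0.00186 and 0.00245 (99.5 and 93.5), with YRA1 at 0.9977, 0.9993 and 0.9994 at the 3 times in Nab2-AA. Random lists were not matched on the starting fraction. In Nab2-AA at 0 min RPL2A stood at 0.874, RPS14B at 0.822, the other RP genes at 0.905 or more and DBP2 at 0.9987. Near 1 a given change in odds moves the fraction little. These medians therefore do not show that RP or RNA processing genes were spared. The 6 ubiquitin and proteasome genes started between 0.631 (UBC9) and 0.800 (RUB1), where the same change in odds moves the fraction more. Their low percentile at 30 min therefore does not show that this list was affected more than others. The 3 snoRNA hosts had -0.00925 and -0.00818 (15.6 and 15.1), among them EFB1 at -0.00892 after 30 min, and the 2 cytoskeleton genes -0.0244 and 0.00198. Of the 57 genes, 35 lay below 0 at both times and 12 above at both. With 1 library per strain and time there was no replicate check, and no test covered the spread between libraries. The fewest reads behind any gene were 951. Fisher's exact test of 10 against 0 min on the reads of each gene covers counting error only. For RPL2A it passed in Control-AA as well as in Nab2-AA (Fisher adjusted p = 7.64e-140 and 4.91e-99). The median difference of changes over the 57 genes was -0.0320 at 10 min and -0.00892 at 30 min. Scaled as in the authors' corrected column it became -0.00895 and -0.0295, from medians of -0.0237 and -0.0403 in Nab2-AA and -0.0142 and -0.00809 in Control-AA, so the order of the time points was not kept.

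**Figure D2:**
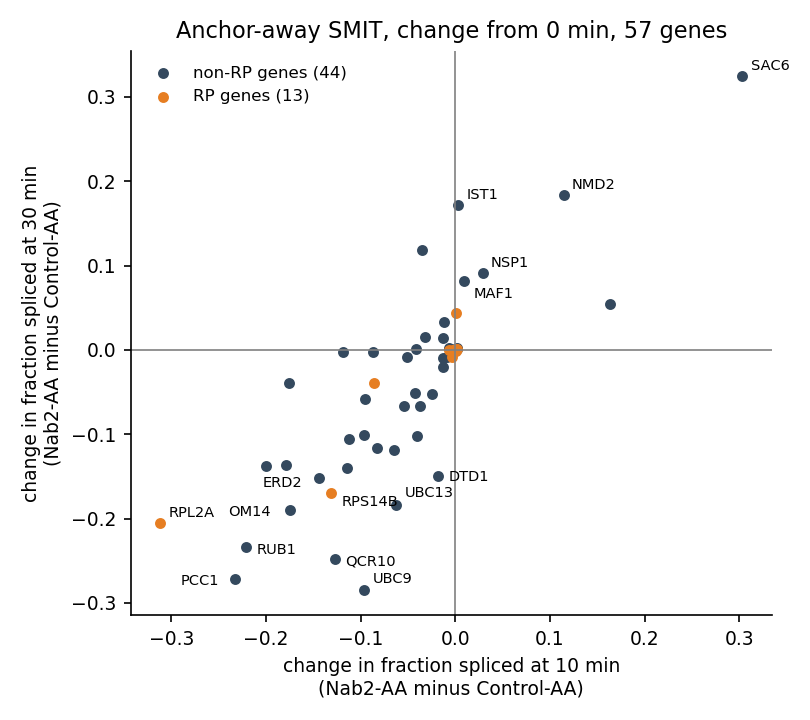
Each point is a gene, placed by its change in fraction spliced from 0 min in Nab2-AA minus that in Control-AA, at 10 min (horizontal axis) and 30 min (vertical axis), with RP genes in orange and others in dark blue. Most named genes lie in the lower left, such as PCC1 at -0.233 and -0.272, while SAC6 lies alone at 0.303 and 0.324.

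Long reads asked, after 10 min of rapamycin, whether introns stayed in transcripts when Nab2 was withdrawn and where those transcripts began and ended. Of reads that spanned an intron, 65.5% ± 0.121 were spliced in Nab2-AA against 75.2% ± 1.30 in Control-AA (SD, n = 2), a difference of -9.68 percentage points. The 4 libraries gave 65.5% (exact 95% interval 64.9 to 66.0) and 65.6% (64.7 to 66.6) in Nab2-AA, and 74.3% (73.4 to 75.2) and 76.2% (75.4 to 76.9) in Control-AA. RP introns were spliced in 76.0% ± 0.338 of reads against 84.7% ± 0.564, and other introns in 46.1% ± 0.262 against 56.8% ± 2.47. The differences exceeded the spread between libraries, but an exact permutation test of 2 against 2 cannot go below a two-sided p of 0.3333, the value it gave. Among reads that were not chimeric and ended within 250 nt of the coding end, the difference was only -2.56 points, 79.1% ± 0.439 against 81.7% ± 1.36.

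**Figure D3:**
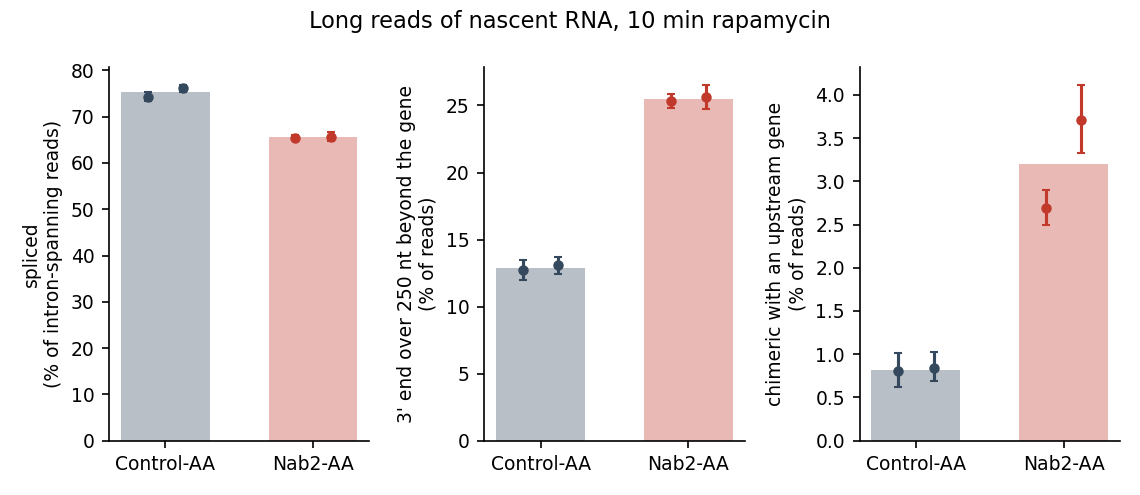
Bars are means of 2 long-read libraries per strain, points are single libraries with exact 95% binomial intervals, and the vertical axes give the percentage of reads that were spliced, that ended over 250 nt beyond the gene, and that were chimeric with an upstream gene. Nab2-AA lies below Control-AA in the first panel (65.5% against 75.2%) and above it in the others (25.5% against 12.9%, and 3.20% against 0.822%).

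Intron by intron, 15 of 197 introns fell in Nab2-AA and 0 rose. The counts include reads ending beyond the gene, whose share rose in Nab2-AA, and no fit per intron left them out. RPL21B, a large-subunit ribosomal protein gene (intron at XVI 406647 to 407067), fell from 86.8% ± 4.27 to 56.3% ± 3.15 spliced (SD, n = 2; log2 odds ratio -2.21, adjusted p = 3.03e-07 in edgeR). TEF4, a subunit of translation elongation factor 1B whose intron holds a snoRNA (XI 283096 to 283421), fell from 83.3% ± 4.08 to 66.7% ± 0.439 (edgeR adjusted p = 0.000257), and RPS18A (IV 1359970 to 1360404) from 79.6% ± 2.34 to 62.9% ± 3.74 (edgeR adjusted p = 0.000646). RPL2A (VI 221268 to 221414) fell from 96.6% ± 1.502 to 87.3% ± 0.722 and TAF14, a subunit of several transcription complexes (XVI 305307 to 305411), from 56.0% ± 18.6 to 8.89% ± 4.26. ASC1, the ribosome-bound RACK1 protein, fell from 87.4% ± 1.13 to 75.7% ± 1.51, RPL16A from 92.7% ± 1.44 to 82.5% ± 1.16, RPL28 from 71.9% ± 0.845 to 57.1% ± 1.51, and RPL25 from 83.2% ± 4.33 to 68.9% ± 4.64. RPS17A fell from 90.6% ± 4.42 to 76.1% ± 6.15, RPS19B from 79.8% ± 9.59 to 64.1% ± 5.84, EFB1, another elongation factor subunit (I 142254 to 142619), from 77.7% ± 7.84 to 67.8% ± 2.84, and ARP9 from 52.1% ± 26.5 to 21.9% ± 3.75. The remaining calls, RPL19B (93.3% ± 0.737 to 85.5% ± 3.72) and RPS7A (96.9% ± 0.525 to 91.4% ± 1.34), like RPL2A, had smaller changes than the rule for named introns takes and are named because all calls are. ACT1 (VI 54378 to 54686) had 83.3% ± 1.03 against 86.8% ± 1.69 and did not pass (edgeR adjusted p = 0.214). All these introns lie within the coding span of their genes (sacCer3).

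By list, 10 of 89 RP introns fell (13 adjusted over the list alone) and 5 of 108 others (5). Of 9 introns in snoRNA host genes 3 fell (4 adjusted over the list alone), those of TEF4, ASC1 and EFB1. In membrane traffic 0 of 9 passed (1 adjusted over the list alone), where SEC14 had 58.3% ± 11.8 against 82.1% ± 11.9 (edgeR adjusted p = 0.0510) and SEC27 54.6% ± 6.49 against 46.4% ± 1.35. The counts were 0 of 6 in the cytoskeleton list, which included TUB1 at 63.4% ± 7.13 against 76.0% ± 4.31, 0 of 5 in ubiquitin and proteasome, with UBC4 at 31.6% ± 10.9 against 20.3% ± 2.97, 0 of 7 in RNA processing and export, with YRA1 at 12.0% ± 0.431 against 16.3% ± 2.86, and 0 of 3 in mitochondrial respiratory, with QCR9 at 9.34% ± 9.49 against 16.3% ± 12.2. It was also 0 of 14 in genes with 2 introns, and each of these zeros was the same adjusted over the list alone; no meiotic gene had enough reads. In all, 147 of 197 log2 odds ratios lay below 0 and 40 introns had an unadjusted p under 0.05. DESeq2 called 2, and edgeR called 3 without Nab2-AA replicate 1, 8 without Nab2-AA replicate 2, 9 without Control-AA replicate 1 and 2 without Control-AA replicate 2; limma on the authors' fractions called 0. The log2 odds ratio itself depended on the Control-AA libraries for 3 introns: without replicate 1 and without replicate 2 of Control-AA it was -1.18 and -0.24 for EFB1 (-0.77 with all), -3.01 and -0.76 for ARP9 (-2.10), and -0.71 and -1.96 for RPS19B (-1.15). Only RPL21B among the 15 kept its call whichever library was left out, and without chimeric reads 9 introns were called. Among the lost calls the log2 odds ratio shrank from -2.21 to -0.78 for RPL21B, from -1.99 to -0.59 for RPL2A and from -3.65 to -2.35 for TAF14 (edgeR adjusted p = 0.310, 0.474 and 0.246). It hardly moved for ARP9 (-2.10 to -1.95), RPS19B (-1.15 to -1.11) and RPL28 (-0.96 to -0.96), whose edgeR adjusted p became 0.0531, 0.0794 and 0.0503.

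**Figure D4:**
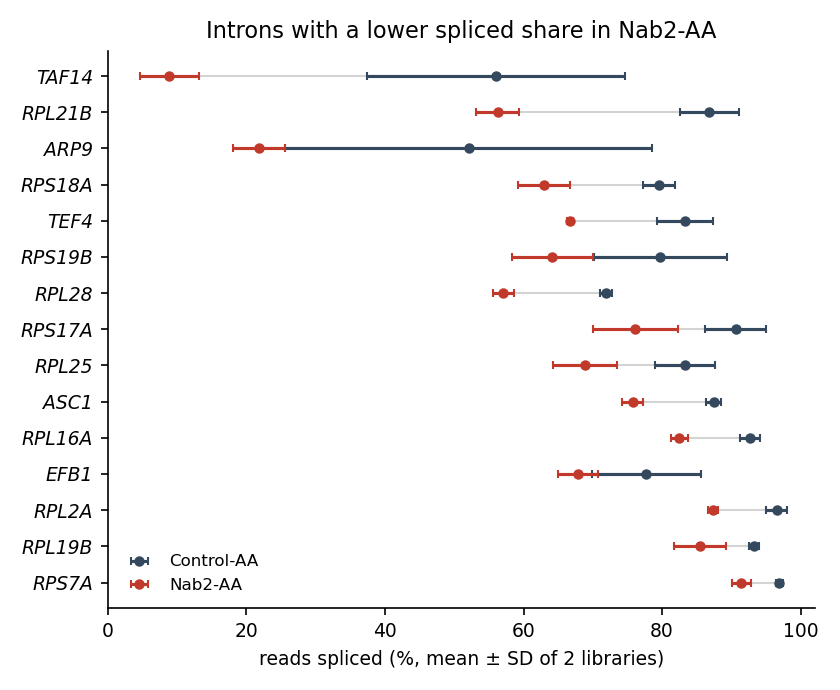
For each of the 15 introns called lower in Nab2-AA (vertical axis), points give the percentage of reads spliced (horizontal axis) as the mean and bars the SD of 2 libraries, Control-AA in dark blue and Nab2-AA in red. Nab2-AA lies to the left throughout, from 8.89% against 56.0% for TAF14 to 91.4% against 96.9% for RPS7A; the bars meet for ARP9 and EFB1 and nearly do for RPS19B.

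Reads whose 3' end lay more than 250 nt past the coding end made up 25.5% ± 0.221 of reads in Nab2-AA and 12.9% ± 0.248 in Control-AA (SD, n = 2), a ratio of 1.98. Transcript ends were not in the reference used, so a read that ended inside a long 3' untranslated region counts here too. In RP genes the share was 19.2% ± 0.236 against 6.95% ± 0.117, and in other genes 37.1% ± 1.02 against 24.3% ± 0.665. RPS18A rose from 7.17% ± 3.57 to 36.1% ± 2.33 (edgeR adjusted p = 1.34e-15), ASC1 from 5.02% ± 0.463 to 25.1% ± 0.348, and RPS9A from 11.8% ± 5.17 to 48.1% ± 2.12. RPL25 rose from 13.9% ± 3.23 to 40.9% ± 1.83, RPL16A from 3.51% ± 0.564 to 20.6% ± 1.31, YRA1, an mRNA export factor, from 21.1% ± 2.40 to 42.1% ± 0.426, and RPO26 from 46.7% ± 15.5 to 95.3% ± 0.973. ACT1 also rose, from 5.19% ± 0.832 to 13.4% ± 2.07 (edgeR adjusted p = 2.62e-06), and VPS75, a histone chaperone, was the single gene that fell, from 84.6% ± 21.8 to 44.0% ± 0.683 (edgeR adjusted p = 0.0327). The chimeric share of VPS75, given below, rose from 0% to 44.0% ± 0.683. Whether its fall here reflects those added reads was not tested. The genes named in this paragraph were chosen after their values were seen.

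The test per gene was added after the shares were seen. edgeR called 62 of 179 genes higher and 1 lower, with a median rise of 14.7 points among the 62, and 83 genes had an unadjusted p under 0.05. Of 87 RP genes 48 rose (54 adjusted over the list alone), of 92 others 14 rose and 1 fell (11 and 0), and of 7 snoRNA hosts 4 rose (6). The other lists gave 2 of 5 cytoskeleton genes (2), 1 of 5 in ubiquitin and proteasome (1), where UBC4 went from 66.6% ± 18.3 to 77.2% ± 3.14 (edgeR adjusted p = 0.0156), 1 of 7 in RNA processing and export (1), 1 of 3 in mitochondrial respiratory (1) and 0 of 8 in membrane traffic (0). For UBC4 the Control-AA libraries lay further apart than the strain means. Of the genes of the 15 lower introns, 12 also rose here. Reads ending beyond the gene were spliced in 32.6% ± 1.47 in Nab2-AA and 35.3% ± 1.84 in Control-AA. Reads that were not chimeric and ended within 250 nt were at 79.1% ± 0.439 and 81.7% ± 1.36. A rise in the former lowers the spliced share by itself, so this overlap is not independent support. DESeq2 called 10, and edgeR called 20 without Nab2-AA replicate 1, 26 without Nab2-AA replicate 2 and 36 without Control-AA replicate 2. The share itself was compared only by exact permutation (p = 0.3333, the smallest that 2 against 2 libraries give).

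Chimeric reads, which overlapped the intron-containing gene and an upstream gene on the same strand by at least 50 nt each, made up 3.20% ± 0.719 of reads in Nab2-AA against 0.822% ± 0.0306 in Control-AA (SD, n = 2), a ratio of 3.90. The share rose for RPL21B from 1.68% ± 0.322 to 30.1% ± 0.311, where 110 reads in Nab2-AA and 3 in Control-AA also covered the upstream RPS9A (edgeR adjusted p = 1.57e-07). It rose for RPL2A from 0.187% ± 0.265 to 8.59% ± 0.414, with RRT5 upstream in 70 reads against 1 (edgeR adjusted p = 4.44e-08). For TAF14 it rose from 3.85% ± 5.44 to 63.2% ± 18.7, in 25 reads against 0 with RPL5. For VPS75 it reached 44.0% ± 0.683 in 18 reads, all with CRS1, against 0 of 24 reads in Control-AA, which allows a share of up to 12.5% (edgeR adjusted p = 0.0265 for TAF14 and VPS75).

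The most chimeric reads in Nab2-AA came from MUD1, a U1 snRNP protein gene downstream of TEF2, at 91.5% ± 0.447 against 81.3% ± 1.84 (edgeR adjusted p = 0.519). MOB2, a kinase activator downstream of RPL22B, had 82.7% ± 7.03 against 39.3% ± 5.05 (edgeR adjusted p = 0.105), and SAC6, downstream of FIN1, 15.4% ± 3.74 against 8.24% ± 4.28; none of these passed. By list, 2 of 38 RP genes and 2 of 43 others rose, the same adjusted over the list alone, and 0 in the lists of snoRNA hosts, cytoskeleton, membrane traffic, ubiquitin and proteasome, RNA processing and export, and mitochondrial respiratory, also adjusted over the list alone. Of 81 genes tested, 4 were called higher and 0 lower, 11 had an unadjusted p under 0.05, and DESeq2 called 1. edgeR called 1 without either Nab2-AA library, 2 without either Control-AA library, and only RPL21B passed in each case. The exact permutation p of the share was 0.3333.

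Within the same introns, chimeric reads were spliced far less often than other reads in every library. The Mantel-Haenszel odds ratio over introns was 0.0755 (95% interval 0.0559 to 0.102) and 0.0869 (0.0565 to 0.134) in Nab2-AA and 0.0764 (0.0238 to 0.245) and 0.0383 (0.0133 to 0.110) in Control-AA. Without RP genes it was closer to 1, at 0.286 and 0.255 in Nab2-AA and 0.0970 and 0.0930 in Control-AA, with a mean over libraries on the log scale of 0.160 against 0.0662. Summed over these introns, 8.08% and 7.69% of chimeric reads in Nab2-AA were spliced against 72.2% and 71.8% of other reads. In Control-AA it was 5.88% and 5.10% against 76.9% and 80.3%. Unlike the odds ratio, these sums are not stratified by intron and also reflect which introns gave chimeric reads. The difference between the strains in this odds ratio was not tested; Control-AA had 4 and 5 spliced chimeric reads. Among reads that were not chimeric, 67.4% ± 0.586 were spliced in Nab2-AA against 75.8% ± 1.34 in Control-AA (SD, n = 2). For introns whose nearest upstream neighbour lies on the same strand the difference in the spliced share was -9.72 points, and on the opposite strand -9.59 points. In non-RP introns it was -12.8 and -8.47. Over all introns, RP included, but without chimeric reads it was -7.36 and -9.12. RPL21B, whose chimeric reads reach RPS9A, counts as opposite strand because YPL080C lies nearer. These classes therefore separate genes by run-in from upstream only in part. In the largest library, leaving out chimeric reads took the same-strand class from 12946 to 12342 reads. The opposite-strand class went from 13688 to 13578, so most chimeric reads lay in the same-strand class.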

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

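All tests named in this part were chosen only after the result was seen, except that of near-complete splicing, whose prediction was written before. In single genes Nab2-AA and Control-AA moved in opposite directions at both times after rapamycin, with 1 library per strain and time, so the difference was not tested. Nab2-AA minus Control-AA at 30 min was -0.272 for PCC1, -0.234 for RUB1, -0.205 for RPL2A and -0.150 for DTD1. It was 0.324 for SAC6, 0.184 for NMD2, 0.0911 for NSP1 and 0.00245 for YRA1, whose counting interval includes 0 (-0.00350 to 0.00840). Between deletion strains the median change had opposite signs in both replicate numbers for gbp2 and tho2 (0.0407 apart) and for tho2 and htz1 (-0.0326); these differences were not tested, and both strains of a pair share the wild-type libraries. The gbp2 median in replicate 2 was only -0.000101, and with the authors' correction the medians of both numbers were positive in gbp2 (0.0174 and 0.0167), tho2 (0.0925 and 0.0690) and htz1 (0.0417 and 0.0269), so the opposite signs were gone. Reads starting over 250 nt upstream of the coding start were more frequent in Nab2-AA by 3.32 percentage points, 5.76% ± 0.765 against 2.44% ± 0.0677 (SD, n = 2). Chimeric reads, which reach an upstream gene, differed by 2.38 points, and whether the 2 classes are separate signals cannot be told. The overlap of these read classes was not counted.

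The lower spliced share in Nab2-AA long reads could come from reads that run in from upstream or on past the gene, or from the strains themselves. Without chimeric reads the difference was -8.36 points against a combined SD of 1.46, so reads called chimeric were not its whole cause. Any run-in reads that covered too little of the upstream gene to be called chimeric stayed in. Reads starting over 250 nt upstream of the coding start made up 5.76% in Nab2-AA and 2.44% in Control-AA. Reads called chimeric made up 3.20% and 0.822%. The test therefore cannot decide on run-in reads as a whole. Among reads that were not chimeric and ended within 250 nt the difference was -2.56 against 1.43. Leaving out reads called as ending beyond the gene thus took away most of the difference. Any reads that ran past the transcript end but ended within 250 nt of the coding end stayed in. The test therefore cannot decide whether reads running past the gene were the whole cause. The remainder is small and leans on 1 library (78.8% and 79.4% in Nab2-AA, 80.7% and 82.7% in Control-AA). In SMIT the strains differed by a median of -0.0120 at 0 min and -0.0401 at 10 min, from 1 library each, so a difference before rapamycin cannot be told from an effect of it.

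The authors' difference tables hold 111 values of 592 that repeat the value of the gene listed directly above. Shuffled orders gave at most 15 repeats (permutation p = 0.0001, the smallest that 10000 shuffles allow), which fits values carried over from the line above. Genes near complete splicing could have given no value of their own. The median wild-type fraction differed by -0.174 between genes with and without a repeat (permutation p = 0.145). The 3 genes that repeat most had wild-type SMIT fractions near 1 (GLC7 in 12 of 12 tables at 0.993, RPL35A in 10 at 0.998, YRA1 in 7 at 0.989). The data therefore cannot tell. These tables entered no test here.

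In SMIT, fractions of the deletion strains were lower in replicate 1 than in replicate 2 by a mean of -0.0987 over the 6 strains. With the authors' correction the gap was -0.0823 (SD over strains 0.0346), so the correction does not remove it. The run could explain it, but replicate number and run coincide, and the wild type had a gap of -0.0409, so the data cannot tell.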

How the results depend on the processing

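Alternatives marked here as added, and their tests, were chosen only after the result was seen. Under 549 alternatives no called intron, no gene called for its chimeric share and no long-read share changed direction, while medians of deletion strains, which lie within the spread of their libraries, did change sign. In the deletion strains all counts stayed at 0 under leave-one-out. A replicate block gave 3 genes in tho2; DESeq2 gave 1 in rtt103 and 1 in tho2; limma 1 each in rtt103, tho2, pub1 and htz1; a fit of only the wild type and the strain 1 in tho2 and 2 in pub1. Added settings gave 1 in gbp2 and 2 in tho2 with the run as block, and 3 in rtt103 and 23 in tho2 with the authors' correction and the replicate block. Deviations of same-numbered libraries correlated at 0.282 to 0.852 among deletions and at 0.0171 to 0.560 between these and the wild type, whose replicate 1 had its own run. The deletion libraries thus share runs by number, but a comparison with the wild type is paired in replicate 2 alone, so the block is given as an alternative. Filters on reads removed no gene there. For introns in long reads the replicate block gave 7 and the added crossed block 0 (replicate numbers correlated at -0.105), DESeq2 2, limma on the authors' fractions 0, reads that were not chimeric 9, and leave-one-out 2 to 9. For the chimeric share the block gave 2 genes, DESeq2 1 and leave-one-out 1 to 2; for reads ending beyond the gene the block gave 34, DESeq2 10 and leave-one-out 20 to 47. Where 1 library was left alone in an arm it was assumed to vary like the others. With the authors' correction (added) the median changes of all 6 strains became positive, at 0.0828 in tho2, 0.0343 in htz1, 0.0211 in gbp2, 0.0316 in rtt103, 0.00585 in npl3 and 0.0561 in pub1; with the block besides tho2 had 0.0808 and htz1 0.0343, and the authors' score, on another scale, gave 0.0380 in gbp2 and 0.0624 in htz1. Leaving out 1 library turned the sign of the median in every strain. The time course at 10 min moved to -0.0179 with 60-nt bins, -0.0296 without bins, -0.0247 within 300 nt, -0.00895 corrected and -0.266 in the authors' score; at 30 min to -0.0125 without bins, -0.0101 within 300 nt, -0.0295 corrected and -0.125 in the authors' score. Replicate numbers cannot pair the time course, which has 1 library per strain and time; a fit that pairs the strains by time would test a strain difference, not the change after rapamycin, and was not made. The difference in spliced share became -6.23 unweighted over introns, -11.1 with identical alignments counted once, -8.36 without chimeric reads and -2.56 also without reads ending beyond the gene (leave-one-out -10.6 to -8.77). The chimeric share difference became 3.50 unweighted and 4.06 among genes whose nearest upstream neighbour lies on the same strand (leave-one-out 1.87 to 2.89). That class leaves out RPL21B, whose nearest upstream neighbour lies on the opposite strand. Reads ending beyond the gene became 11.02 at a shorter distance of 150 nt, 10.6 at a longer distance and 14.9 with identical alignments counted once (12.4 to 12.8). The odds ratio of splicing in chimeric reads was 0.160 without RP genes (0.0604 to 0.0794). Except for fewer libraries or reads by construction, the cause was not tested.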

Other observations

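The tests in this part were chosen only after the result was seen. Set against the mean of the other 5 deletions, with the run in the labels as block, tho2 had 8 genes with higher splicing and npl3 had 3 with lower. In npl3 the genes were EFB1 (log2 odds ratio -1.19), which codes for an elongation factor subunit, SEC17 (-1.33), a factor of vesicle fusion, and OM14 (-1.51), of the mitochondrial outer membrane, with edgeR adjusted p = 0.0269, 0.0269 and 0.0297. In tho2 they were IST1 (1.49, edgeR adjusted p = 0.00688), OM14 (1.26), RPS27B (1.26), IMD4 (1.18), QCR10 (1.14), QCR9 (1.07), EFB1 (1.06) and RPP1B (0.89). In htz1 EFB1 was lower (-1.06) and DBP2 higher (2.79), and the other strains had 0 calls. With the authors' correction the same contrast called 3 lower genes in npl3, 9 higher in tho2 and 0 in htz1. Against the wild type EFB1 ran the other way in npl3 (log2 odds ratio 1.43, 0.991 ± 0.00615 against 0.981 ± 0.00577) and in htz1 (1.54), without a call. These contrasts leave the wild type out, and a change in the other deletions would move them as well.

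Reads of RPS24A, a ribosomal protein gene, that ended beyond the gene rose from 7.45% ± 10.5 to 28.5% ± 9.73 (SD, n = 2; edgeR adjusted p = 0.0127), while the chimeric share of its downstream neighbour YOS1, a protein of vesicle transport, did not pass, at 73.1% ± 1.31 (33 of 45 reads) against 62.5% ± 53.0 (4 of 7; edgeR adjusted p = 0.660). Reads ending beyond RPL22B, upstream of MOB2, were at 74.7% ± 7.49 against 41.7% ± 11.8 and did not pass either (edgeR adjusted p = 0.0650).

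Across 48 genes measured in both assays at 10 min, the change in SMIT and in long reads had a Spearman's rho of 0.210 (permutation p = 0.157), and 27 genes were below 0 in both. This cannot tell whether the assays order genes alike. Their levels were far apart for some genes in Nab2-AA at 10 min. The SMIT fraction was 0.9993 for YRA1, 0.9998 for GLC7 and 0.889 for RPS9A, against 12.0%, 28.4% and 8.74% spliced in long reads. RPL2A went the other way, at 0.748 against 87.3%. The reason was not tested, so a SMIT fraction near 1 need not mean complete splicing.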
